A study of Mus musculus with 4 samples.

How the data were processed

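Single-cell TCR libraries were prepared from sorted large intestinal T cells of 2 mice with the 10x Chromium Next GEM V(D)J kit, version 1.1, for mouse T cells, per the labels' protocols. Cell Ranger and the build GRCm38 are named in the submitters' processing notes; the version of Cell Ranger is not given in the sources used here. For each of the 4 libraries the authors deposited a contig table with the count of UMIs and of reads behind each assembled TRA or TRB chain, and a clonotype table with the count of cells per clonotype and its fraction of the library, per the file headers. All 9254 contigs were marked as belonging to a cell, of high confidence, full length and productive. In all libraries the deposited count of cells per clonotype equalled the number of barcodes that named it in the contig table. No gene expression was used here.

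Libraries were grouped by the cell subtype in the labels, and the mouse was taken from the sample titles. Both subsets of a mouse come from the same animal, so the libraries are paired by mouse; with 2 mice the deviations of same-mouse libraries (r = 0.049 across 93 segments) are equal in size by construction and say nothing more. The mice are the replicates. How many donors the transferred cells came from is not given in the sources used here.

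For each cell the TRA and TRB contigs with most UMIs were taken. Cells needed both chains, at most 1 TRB and at most 2 TRA. No doublet caller was run, so this limit on chains was the only filter against doublets, and doublets in which 1 TRB was read stay in the data. This left out 133, 284, 194 and 232 cells without TRA and 98, 99, 55 and 108 without TRB in regulatory and effector cells of mouse 1 and regulatory and effector cells of mouse 2, and 4, 17, 55 and 17 with extra chains. A clonotype was the V segment and CDR3 nucleotide sequence of both chains. Contigs named for TRBV12-2 and TRBV13-2 together had the same framework 1, CDR1 and CDR2 as those named TRBV13-2 alone (1 sequence in 567 contigs) and were counted as TRBV13-2. The median depth was 4 UMIs per TRA contig and 5 to 7 per TRB contig, and 5.57 to 6.75% of contigs rested on 1 UMI. Shares of a single library have 95% exact Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 cells of the total allow; both cover counting error only. Cells of 1 clone descend from a common cell, so cells are not independent draws.

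Richness was the expected number of clonotypes among 521 cells, the size of the smallest library. It was tested against drawn cells in 20 simulated libraries, where it was off by at most 0.282%. Single values were compared with two-sided exact permutation tests over libraries. Segment usage was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the number of distinct clonotypes per segment, with the log total of the segment class (TRAV, TRAJ, TRBV or TRBJ) as offset, segments with at least 10 clonotypes, and Benjamini-Hochberg adjustment. In 50 simulations of the 93 segments with 20 changed, 20.2% of 2-fold and 79.2% of 4-fold changes were called, all with the right sign, and 0.96% of unchanged segments were called. The estimated common dispersion was 9.77e-05, close to none, so the test rests mainly on counting error. The simulated libraries of a subset likewise differed by little more than counting error, so these rates hold only for mice that vary no further. Similarity was the Jensen-Shannon divergence, set beside 1000 random draws from the pooled pair. For TRBV usage the regulatory libraries, at 0.0866 bits, lay above the 95% quantile of these draws, 0.0817, and so varied beyond counting error. The effector libraries, at 0.0269 bits, lay under theirs, 0.0540. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 was used, and figures were drawn with matplotlib 3.10.9. All 153 segments matched a gene symbol or synonym in the RefSeq table for GRCm38.p6, from which positions were taken.

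Before the data were examined, the tests, the alternatives and the items to name were fixed. Named segments were all that passed the threshold, the 4 most used TRBV and TRAV segments, and 3 lists: the Vbeta8 family, superantigen-reactive TRBV segments, and TRBV segments of microbiota-reactive T cells. Named clonotypes were the 3 largest of each library and up to 3 shared by the subsets of each mouse; other clonotypes were named after their values were seen. Alternatives were other clonotype definitions (TRB only, amino acid CDR3, the deposited clonotypes), cells with extra chains kept, at least 3 UMIs per chain, cells in place of clonotypes, other filters, TMM, DESeq2 1.42.0, merged TRAV subgroups, a block for the mouse, and each library left out.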

Results

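Paired T cell receptor (TCR) sequences were read from single large intestinal CD4+ T cells of 2 RAG2-deficient mice, which lack T and B cells of their own. Each mouse had received naive FoxP3- and regulatory FoxP3+ CD4+ T cells together, and 7 weeks later FoxP3+ (regulatory) and FoxP3- (effector) cells were sorted from the same intestine. There was 1 library per subset and mouse, so that each subset had n = 2 mice. The libraries held 756 regulatory and 1416 effector cells from mouse 1 and 1048 regulatory and 1716 effector cells from mouse 2. Total UMIs were 6791, 15372, 11232 and 19606 in the same order, with a median of 8 to 10 UMIs per cell. A cell entered the comparisons with 1 productive TRB chain and 1 or 2 productive TRA chains, which kept 521, 1016, 744 and 1359 cells. These fell into 135, 206, 181 and 226 clonotypes, a clonotype being the set of cells with the same V segments and CDR3 nucleotide sequences in both chains.

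The first comparison asked how far regulatory and effector cells that had lived in one intestine shared their receptors. The repertoires were almost separate. In mouse 1, 3 clonotypes were found in both subsets, comprising 6 of 521 regulatory cells (1.15%, 95% Clopper-Pearson interval 0.42 to 2.49%) and 75 of 1016 effector cells (7.38%, 5.85 to 9.17%). In mouse 2 no clonotype was found in both, with 0 of 744 regulatory cells, which allows a share of up to 0.403%, and 0 of 1359 effector cells, which allows up to 0.221%. In the pooled cells of both mice, 0.474% of regulatory and 3.16% of effector cells carried a receptor of the other subset, all of them in mouse 1. No interval is given for the pool, as the mice differed and cells of 1 clone are not independent. With at least 3 UMIs per chain these shares were lower, at 1 of 314 regulatory (0.318%) and 12 of 669 effector cells (1.79%) in mouse 1 and at 0.131% and 0.754% over both mice.

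The 3 clonotypes of mouse 1 were unequally divided. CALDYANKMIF/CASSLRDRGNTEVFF (TRA and TRB CDR3, with TRAV12-2 and TRBV3) was the second largest effector clonotype with 54 cells, and it had 1 regulatory cell. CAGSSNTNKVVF/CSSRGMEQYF (TRAV7-1 and TRBV30) had 20 effector cells and 1 regulatory cell. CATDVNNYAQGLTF/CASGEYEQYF (TRAV8-1 and TRBV13-2) had 4 regulatory cells, 1 effector cell and 2 regulatory cells in mouse 2. With clonotypes counted as shared only when the other library held at least 2 of their cells, an alternative chosen after the data were seen, the shares were 0.158% of regulatory and 0.042% of effector cells. No test was made, since 2 mice allow only 2 pairings.

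**Figure D1:**
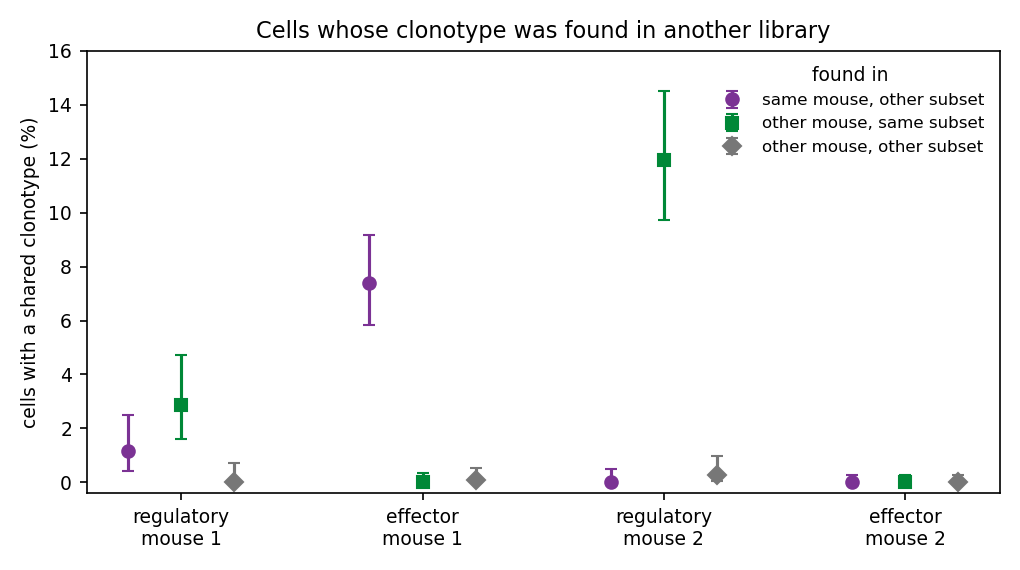
Percent of cells in each library (x axis) whose paired clonotype was also found in another library (y axis), with 95% Clopper-Pearson intervals; colours and symbols give the library searched. The highest share, 12.0%, belongs to regulatory cells of mouse 2 searched in regulatory cells of mouse 1.

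Across the mice, the regulatory libraries had 5 clonotypes in common, which held 15 of 521 cells in mouse 1 (2.88%, 1.62 to 4.70%) and 89 of 744 cells in mouse 2 (12.0%, 9.72 to 14.5%). With at least 3 UMIs per chain the shares were 3 of 314 cells (0.955%, 0.197 to 2.77%) and 45 of 447 cells (10.1%, 7.44 to 13.2%). Of these, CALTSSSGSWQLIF/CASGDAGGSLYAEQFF (TRAV12D-2 and TRBV13-2) was the second largest regulatory clonotype of mouse 2 with 82 of these 89 cells, and it had 5 cells in mouse 1. No test compared this sharing with that within a mouse. The effector libraries had 0 paired clonotypes in common, which allows up to 0.295% of effector cells in mouse 1. By the amino acid sequence of the TRB CDR3 alone, the regulatory libraries shared 6 sequences, which include those of the 5 paired clonotypes. They were 6 of 128 in mouse 1 (4.69%, 1.74 to 9.92%) and 6 of 167 in mouse 2 (3.59%, 1.33 to 7.66%). The effector libraries shared 1 sequence, of 187 in mouse 1 (0.535%, 0.014 to 2.94%) and of 213 in mouse 2 (0.469%, 0.012 to 2.59%). Effector cells of mouse 1 and regulatory cells of mouse 2 also shared 1. Regulatory cells of mouse 1 and effector cells of mouse 2 shared 0. No TRB CDR3 sequence was found in all 4 libraries, 1 was found in 3 and 8 in 2. Only 1 of these 9, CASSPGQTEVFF of the effector libraries, was encoded by more than 1 nucleotide sequence.

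The second comparison asked whether the subsets differed in clonal expansion. Large clones filled a substantial part of every library. The 10 largest clonotypes held 50.1% and 49.6% of regulatory cells in mice 1 and 2 (49.8 ± 0.35%, SD, n = 2), and 37.1% and 66.2% of effector cells (51.7 ± 20.6%, SD, n = 2). The effector cells of mouse 1 were the most even library, with an inverse Simpson index of 47.1 against 9.38 in the effector cells of mouse 2 and 18.3 and 18.9 in the regulatory libraries. The difference between the subsets thus took opposite signs in the mice.

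In regulatory cells of mouse 1 the leading clonotypes were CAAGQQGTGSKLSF/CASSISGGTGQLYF (TRAV19 and TRBV19, 93 cells), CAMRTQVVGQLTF/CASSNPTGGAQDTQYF (57 cells) and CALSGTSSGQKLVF/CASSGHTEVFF (29 cells). In regulatory cells of mouse 2, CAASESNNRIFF/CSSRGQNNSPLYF (TRAV14D-3-DV8 and TRBV30) had 125 cells, ahead of the clonotype shared with mouse 1 and of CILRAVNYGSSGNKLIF/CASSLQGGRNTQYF (63 cells). Effector cells of mouse 1 were led by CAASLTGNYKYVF/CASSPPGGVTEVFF (TRAV7D-2 and TRBV26, 65 cells), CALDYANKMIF/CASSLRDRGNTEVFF and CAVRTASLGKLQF/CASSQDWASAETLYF (51 cells). In effector cells of mouse 2 both leading clonotypes carried the same TRBV13-1 chain, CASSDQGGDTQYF, with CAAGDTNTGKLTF in 313 cells and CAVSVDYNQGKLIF in 227 cells as the TRA with most UMIs. Both TRA chains were detected together in many of these cells, and the authors' deposited table lists them as 1 clonotype of 613 cells, 35.7% of the library. The next clonotype there was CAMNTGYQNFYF/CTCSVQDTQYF (TRBV1, 197 cells).

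**Figure D2:**
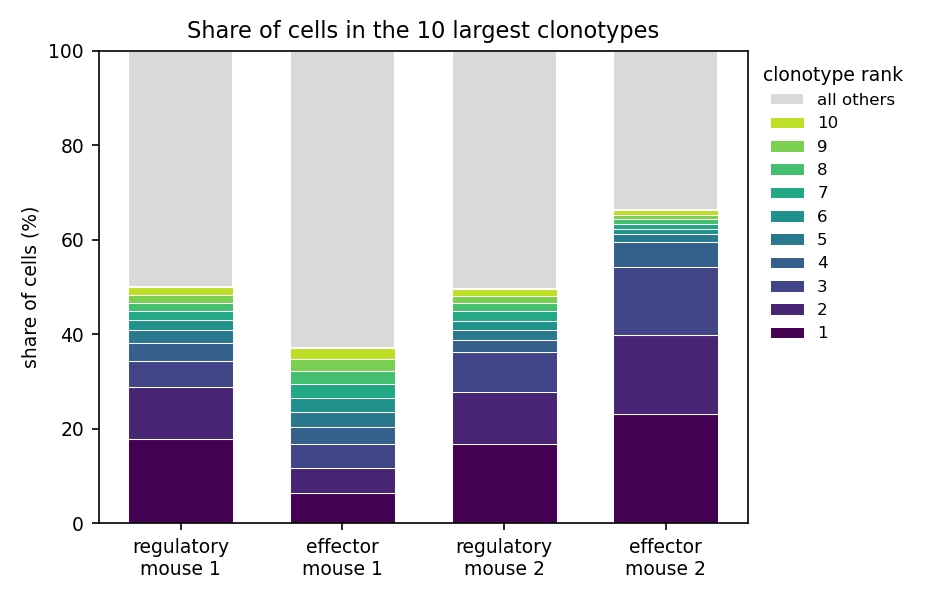
Share of cells (y axis, percent) in each of the 10 largest clonotypes of the 4 libraries (x axis), stacked from the largest at the bottom; grey stands for all other clonotypes. The stacks reach 50.1%, 37.1%, 49.6% and 66.2% from left to right.

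Among 521 cells drawn from each library, the expected number of clonotypes was 135 and 148 in regulatory cells (141 ± 9.0, SD, n = 2) and 145 and 126 in effector cells (135 ± 13.8, SD, n = 2; two-sided exact permutation p = 0.667). Shannon entropy was 5.73 ± 0.15 bits in regulatory and 5.69 ± 1.02 bits in effector cells (SD, n = 2; exact permutation p = 1). The exact permutation p was also 1 for the share of the 10 largest clonotypes. With 2 libraries against 2 there are 6 splits and the smallest exact p is 0.333, so none of these tests could pass 0.05.

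The third comparison asked whether the subsets drew on different V and J segments. In the main unpaired edgeR fit, with every clonotype counted once, regulatory cells used TRBV12-1 and TRBV12-2 more than effector cells. They used TRAV14-3 and TRBV19 less. With the mouse as a block only the TRBV12-1 and TRBV12-2 calls remained, and DESeq2 called 0 segments. TRBV12-1 (GRCm38 chromosome 6, 41113567 to 41114067) was carried by 4 of 135 and 18 of 181 regulatory clonotypes (6.45 ± 4.94%, SD, n = 2). Among effector clonotypes it was carried by 0 of 206 and 1 of 226 (0.22 ± 0.31%). With the clonotypes of both mice pooled the ratio was 30.1, with an exact counting interval of 4.86 to 1241. TRBV12-2 (chromosome 6, 41118864 to 41119364) was carried by 3 and 15 regulatory clonotypes (5.25 ± 4.29%) and by 2 and 1 effector clonotypes (0.71 ± 0.37%). Its pooled ratio was 8.20 (2.39 to 43.5). For both segments together the ratio was 5.34 (1.02 to 52.7) in mouse 1 and 20.6 (5.27 to 177) in mouse 2. Pooled intervals here and below count clonotypes as independent draws, so they leave out the spread between mice. TRBV19 (chromosome 6, 41178589 to 41179048) fell from 11.5 ± 2.52% of effector clonotypes to 4.71 ± 0.37% of regulatory clonotypes, and TRAV14-3 (chromosome 14, 53763196 to 53763694) was carried by 7 and 6 effector clonotypes and by 0 regulatory clonotypes. Counted by cells, TRBV19 turned direction, with a log2 regulatory over effector value of 0.87 that did not pass the test.

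Of 93 segments tested with edgeR's quasi-likelihood test, these 4 passed a Benjamini-Hochberg adjusted p of 0.05. The log2 regulatory over effector value was 4.53 (SE 0.88, adjusted p = 5.58e-05) for TRBV12-1, 2.89 (SE 0.79, adjusted p = 0.0159) for TRBV12-2 and -1.27 (SE 0.39, adjusted p = 0.0308) for TRBV19. For TRAV14-3, at 0 of 316 regulatory clonotypes, usage was at least 3.17-fold lower against a floor of 3 clonotypes over the group (adjusted p = 0.0206 in the edgeR fit), while the exact counting interval of the ratio, 0 to 0.449, also allows a smaller difference. TRAV14-3 is 1 of several near-identical TRAV14 copies, which together made up 40 of 316 regulatory and 69 of 432 effector clonotypes (ratio 0.79, 0.52 to 1.19). With the mouse as a block, TRBV12-1 and TRBV12-2 remained past the threshold (adjusted p = 5.31e-06 and 0.00247), while TRBV19 (log2 -1.29, adjusted p = 0.0510) and TRAV14-3 (adjusted p = 0.0623) did not. DESeq2 called 0 of the 93 segments, with 3 at an unadjusted p under 0.05 against 10 in edgeR; its log2 values were 4.78 for TRBV12-1, 2.89 for TRBV12-2 and -1.34 for TRBV19. With TRAV segments merged by subgroup no segment was called in edgeR, at log2 values of 4.55 (adjusted p = 0.0739), 2.91 (0.130) and -1.27 (0.124) in the same order. TRBV19 was also lost in edgeR with no filter (log2 -1.27, adjusted p = 0.0676) and with extra chains kept (log2 -1.21, adjusted p = 0.0668). Counted by cells, TRBV12-1 (log2 4.90) and TRBV12-2 (1.97) did not pass either (adjusted p = 0.440 and 0.828).

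Each library was also left out in turn, which leaves 1 subset with a single library that is assumed to vary like the other subset. In edgeR no segment was called without either effector library or without the regulatory library of mouse 2. Without the effector library of mouse 1 the log2 values were 3.77 for TRBV12-1, 3.48 for TRBV12-2 and -1.47 for TRBV19, and without that of mouse 2 they were 2.46 for TRBV12-2 and -1.02 for TRBV19, with TRBV12-1 at 0 effector clonotypes. Without the regulatory library of mouse 2, TRBV19 was at -1.37, and TRBV12-1 and TRBV12-2 had too few clonotypes to be tested. Without that of mouse 1, TRBV12-1 and TRBV12-2 passed the threshold (log2 5.10 and 3.46), with the spread estimated from the effector libraries alone, while TRBV19 (-1.21) and TRAV14-3 did not (adjusted p = 0.227 for each).

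**Figure D3:**
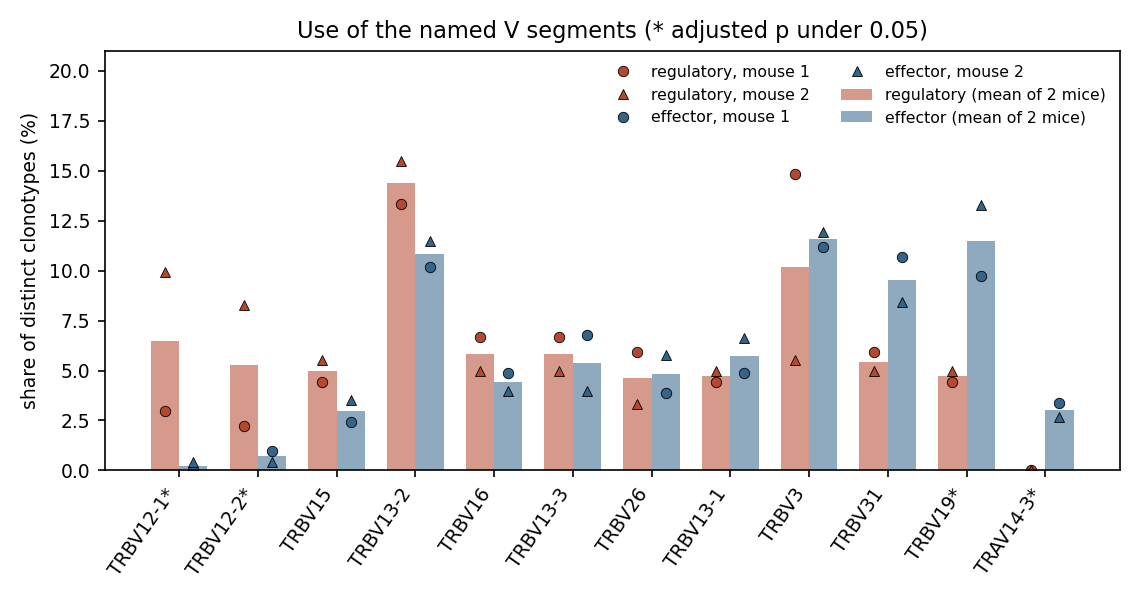
Share of distinct clonotypes (y axis, percent) that used each named V segment (x axis); bars are means of 2 mice, circles mouse 1 and triangles mouse 2, and an asterisk marks an adjusted p under 0.05 in edgeR's quasi-likelihood test. TRBV12-1 and TRBV12-2 reach 9.94% and 8.29% in regulatory cells of mouse 2 and stay at or below 0.97% in effector cells.

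Both TRBV12 segments belong to the fixed list of 5 TRBV segments that react with mouse mammary tumour virus superantigens. The list need not hold every segment with such reactivity, so its share describes these 5 only. Of the 5, 2 rose and 3 did not pass the test, also when adjusted over the list alone: TRBV15 was at 4.98 ± 0.76% of regulatory and 2.98 ± 0.79% of effector clonotypes, TRBV16 at 5.82 ± 1.20% and 4.42 ± 0.62%, and TRBV26 at 4.62 ± 1.85% and 4.82 ± 1.32%. The list as a whole took 22.2% and 32.0% of regulatory and 12.1% and 14.2% of effector clonotypes (exact permutation p = 0.333, the smallest possible). Counted by cells instead, it took 9.40% and 16.3% of regulatory and 23.6% and 10.0% of effector cells. The share of the list takes in TRBV12-1 and TRBV12-2, so it is no separate support for their rise or for the list.

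Of the 2 segments known from microbiota-reactive CD4+ T cells, 0 passed the test, over all segments or adjusted over the list alone. TRBV31, used by T cells against segmented filamentous bacteria, was at 5.45 ± 0.67% of regulatory and 9.54 ± 1.61% of effector clonotypes (adjusted p = 0.389 in edgeR; adjusted over the list alone, 0.0836). TRBV13-1, used by T cells against the CBir1 flagellin, was at 4.71 ± 0.37% and 5.75 ± 1.26%. Together they took 10.4% and 9.94% of regulatory and 15.5% and 15.04% of effector clonotypes, a difference in the same direction in both mice (exact permutation p = 0.333). Of the 3 segments of the Vbeta8 family, 0 passed the test by either adjustment. TRBV13-2 was the most used at 14.4 ± 1.51% and 10.8 ± 0.93%, and TRBV13-3 was at 5.82 ± 1.20% and 5.39 ± 1.99%.

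The remaining frequent segments did not pass the test. TRBV3 was at 14.8% and 5.52% of regulatory clonotypes in mice 1 and 2 and at 11.2% and 11.9% of effector clonotypes. Among TRAV segments, TRAV7D-2 was at 6.84 ± 1.85% of regulatory and 6.45 ± 0.89% of effector clonotypes. TRAV9-1 was at 4.53 ± 0.93% and 3.03 ± 0.53%, TRAV6-6 at 2.67 ± 1.69% and 4.60 ± 1.01%, and TRAV14N-3 at 2.77 ± 0.77% and 4.35 ± 1.35%. Counted by cells, only TRAV14D-3-DV8 passed the threshold, the segment of the largest regulatory clonotype of mouse 2.

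TRBV usage as a whole differed more between the subsets of a mouse than between the mice within a subset, on average 0.103 against 0.057 bits of Jensen-Shannon divergence, with overlapping ranges and no test. By cells that gap fell from 0.047 to 0.022 bits. The divergence was 0.083 and 0.124 bits between the subsets of mice 1 and 2, 0.027 bits between the effector libraries and 0.087 bits between the regulatory libraries. Pairs drawn at random from pooled clonotypes averaged 0.043 bits. The effector pair was the only one of these 4 under the 95% quantile of its random draws. Across both mouse and subset, regulatory cells of mouse 1 and effector cells of mouse 2 were at 0.071 bits. Effector cells of mouse 1 and regulatory cells of mouse 2 were at 0.120 bits. The regulatory library of mouse 1 was thus nearer to each effector library than to the regulatory library of mouse 2. The averages therefore do not mean that the subset ordered all libraries. For TRAV usage the means were 0.205 bits between the subsets of a mouse and 0.170 between the mice, a gap of 0.034 that turned to -0.017 by cells. TRBJ and TRAJ usage gave mean divergences of 0.027 and 0.095 bits between the subsets of a mouse and of 0.025 and 0.093 bits between the mice within a subset.

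Counted once per clonotype, CDR3 properties differed little between the subsets. The mean TRB CDR3 length was 13.9 ± 0.13 residues in regulatory and 13.8 ± 0.063 in effector clonotypes, and the mean TRA CDR3 length was 13.6 ± 0.22 and 13.5 ± 0.038 (SD, n = 2; exact permutation p = 1 for each). Hydrophobic residues at both positions 6 and 7 of the TRB CDR3, an index of self-reactivity, were found in 0 of 135 and 2 of 181 regulatory and in 3 of 206 and 3 of 226 effector clonotypes. A cysteine anywhere after the first CDR3 residue was found in 5.45 ± 0.67% of regulatory and 6.50 ± 0.43% of effector clonotypes (exact permutation p = 0.333, the smallest possible, and 1 after Benjamini-Hochberg adjustment over the 6 CDR3 and joining measures). This count takes in TRBV1 chains that start like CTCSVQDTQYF, so it cannot be read as an index of self-reactivity. It held 8 and 9 regulatory and 14 and 14 effector clonotypes in mice 1 and 2. TRBV1 was carried by 6 and 8 regulatory and 13 and 15 effector clonotypes. TRAJ segments numbered 31 or higher were used by 53.0 ± 1.51% and 53.1 ± 2.49%, and TRBJ2 segments by 64.1 ± 7.82% and 63.6 ± 6.13%. Counted by cells, the regulatory minus effector difference was 0.60 residues for the TRB CDR3 and 0.42 for the TRA CDR3, and -8.13 percentage points for a cysteine after the first residue (exact permutation p = 0.333 for each, the smallest possible). The last value counts the TRBV1 clonotype with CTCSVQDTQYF, which made up 14.5% of effector cells of mouse 2.

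Invariant NKT-like TRA chains (TRAV11 or TRAV11D with TRAJ18) and MAIT-like TRA chains (TRAV1 with TRAJ33) were each found in 0 cells of every library, which allows up to 0.576% and 0.403% of regulatory and 0.295% and 0.221% of effector cells. Cells with 2 TRA chains made up 3.62% and 7.26% of regulatory cells with both chains, and 5.42% and 26.1% of effector cells (exact permutation p = 0.667). Without the TRBV13-1 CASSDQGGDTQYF clone, left out after the data were seen, the share in effector cells of mouse 2 was 4.07% (2.83 to 5.64%). Cells with 2 or more TRB chains made up 0.76% and 6.88% of regulatory and 1.65% and 1.24% of effector cells, and 43 of the 55 such regulatory cells of mouse 2 carried one and the same TRB pair.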

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

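The clonotypes of the report leave out cells with 2 or more TRB chains, and 2 groups of such cells were found in the left-out data above the limit that a count of 0 allows. No doublet caller was run on them. In regulatory cells of mouse 2, 43 of 1048 cells (4.10%, 2.99 to 5.49%) carried both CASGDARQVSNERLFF (TRBV13-2) and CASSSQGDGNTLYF (TRBV29), against a limit of 0.286%. All 43 cells also carried the TRA CDR3 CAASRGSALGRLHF. Their median was 18 UMIs per cell against 9 in the library, and a further 8 and 17 cells carried the first or the second TRB alone. In effector cells of mouse 1, 9 of 1416 cells (0.636%, 0.291 to 1.20%) carried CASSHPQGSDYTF with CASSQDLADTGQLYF, and all 9 also carried the TRA CDR3 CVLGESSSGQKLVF. A further 2 and 0 cells carried the first or the second TRB alone. In each of these libraries the largest other TRB pair had 2 cells. Chance doublets of unrelated cells would not repeat 1 pair so often when so few cells carry either TRB alone. These counts argue against chance doublets for both groups. The UMI counts cannot decide this, as these cells also have more chains.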

How the results depend on the processing

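The largest clonotype alone, all cells of each library, matches of at least 2 cells, deposited segment names and the removal of the largest clone were chosen after the data were seen; depth limits shared clonotypes to those above the stated limits for 0. The cause of the changes below was not tested, except where a library was left out, which removes a replicate. Segment usage gave 4 calls, and 0 with DESeq2, 0 with TRAV segments merged (smallest adjusted p 0.0739), 1 with at least 30 clonotypes (fewer segments tested), 1 with cells counted, 2 with the mouse as a replicate block and 0 to 2 without 1 library; TMM, no filter, extra chains, both-subset clonotypes left out and deposited names gave 3 or 4. Without regulatory replicate 2, TRBV12-1 and TRBV12-2 had under 10 clonotypes and were not tested. Counted by cells, TRBV19 had a log2 value of 0.87, against -1.27. The block changed no other call. Regulatory minus effector differences, none of which could pass 0.05, changed sign as follows. Richness (5.93) was -4.14 by TRB, -7.60 with the deposited clonotypes, -58 over all cells and -3.86 to 15.7 without 1 library. The share of the 10 largest clonotypes (-1.82 points) was 2.36 by TRB, 3.15 with the deposited clonotypes, 2.61 for the largest alone and -16.4 to 12.7 without 1 library. Shannon entropy (0.043) was -0.011 with the deposited clonotypes and -0.68 to 0.77 without 1 library, and inverse Simpson (-9.62) was -28.5 to 9.23. TRAJ position (-0.087 points) was 10.0 by cells, 0.0014 without clonotypes of both subsets, 1.59 with extra chains and -1.85 to 1.68 without 1 library; TRBJ2 (0.47) was -6.27 by cells and -5.06 to 6.0. CDR3 lengths were -0.084 to 0.22 (TRA) and -0.050 to 0.13 (TRB) without 1 library. The share with 2 TRA chains (-10.3 points) was 0.70 without the largest clone of effector mouse 2 and -20.7 to 0.018 without 1 library; that with 2 TRB was -0.68 to 5.44. Sharing within a mouse was 0.131% of regulatory and 0.754% of effector cells with at least 3 UMIs per chain, 0.158% and 0.042% with matches of at least 2 cells, and 0 to 1.15% and 0 to 7.38% for 1 mouse alone. Public effector TRB CDR3 were 0% with the same V segment. The TRBJ divergence between subsets minus that between mice was -0.071 bits by cells, against 0.0017.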

Other observations

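The test of sampling was written before its result was seen, and the other tests below were chosen after.

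V segment usage differed between cells and clonotypes. TRBV12-1 and TRBV12-2 together were carried by 33 of 181 regulatory clonotypes in mouse 2, yet none of the 3 largest clonotypes of that library used them, and the superantigen-reactive list took 16.3% of its cells against 32.0% of its clonotypes. In effector cells of mouse 2 the microbiota-reactive list took 44.3% of cells and 15.04% of clonotypes, because the TRBV13-1 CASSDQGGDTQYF clone belongs to it. TRBV20, outside the rule for named segments and named after its value was seen, was at 2.77 ± 0.77% of regulatory and 6.05 ± 1.05% of effector clonotypes (SD, n = 2; adjusted p = 0.389 in edgeR).

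The regulatory libraries of the mice shared 5 clonotypes and the effector libraries 0. Carry-over of random cells from mouse 2 as the only source is argued against, as the 15 shared regulatory cells of mouse 1 held 5 clonotypes, while 15 random cells of mouse 2 held 11.6 on average and at least 8 at the lower 95% quantile of 10000 draws; their share in the 10 largest clonotypes of mouse 2, 5 of 15 (11.8 to 61.6%), does not differ detectably from the 49.6% of all its cells. Carry-over from mouse 1 stays open for the 4 shared clonotypes other than the largest. Their 7 cells in mouse 2 held 4 clonotypes against 6.11 on average and a lower quantile of 4. Of the 7, 0 belonged to the 10 largest clonotypes of mouse 1 (0 to 41.0%), which held 50.1% of its cells. That share was lower than random cells would give, but the 7 cells are not independent draws, so the 2 measures do not settle it. Independent recombination of the same TRB with an unrelated TRA could not yield these 5 clonotypes, since they were matched in both chains. All 6 TRB nucleotide sequences shared by the regulatory libraries were paired with the same TRA sequence in both, against 2 of 22830 pairs of different TRB sequences. For 5 of the 6 this was the TRA with most UMIs, so the definition of a clonotype had set their match. Only the remaining TRB sequence could have come out otherwise, so no conclusion is drawn. Separate recombination of the same TRA and TRB in both mice, and the hypothesis that both mice received sister cells of clones already expanded in the donors, were not tested.

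The subsets of a mouse shared few clonotypes. Sampling too few cells from 1 common pool does not account for this, since 78.8% to 86.4% of the cells in a random part of a library found their clonotype in the rest of it, while at most 7.23% found it in as many cells of the other subset. Matching on both chains is argued against for mouse 2, as TRB alone gave 0 of 993 regulatory cells. Conversion between the subsets at a rate under these limits, or a few cells sorted into the wrong gate, stay open and were not tested.

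TRBV12-1 and TRBV12-2 were more used by regulatory clonotypes. Strain variants between the transferred subsets stay open for TRBV12-1: 0 of 52 V segments with at least 3 sequences in each subset had a different most common V sequence, but TRBV12-1, with 1 effector sequence, was not among them, unlike TRBV12-2. Whether the regulatory library of mouse 2 was the sole source stays open too, since in mouse 1 TRBV12-1 was carried by 4 of 135 regulatory against 0 of 206 effector clonotypes and TRBV12-2 by 3 against 2 (ratio 2.29, 0.26 to 27.4), and the ratio of both together, 5.34, had a lower bound of 1.02 in a comparison of these libraries and not of the conditions. A difference between regulatory and naive T cells in the donors before transfer is a candidate explanation that was not tested here.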
